A study of Homo sapiens with 4 samples.

How the data were processed

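Human airway epithelial cells from 1 donor were cultured at an air-liquid interface, and 4 cultures were analysed: a control without IL-13 and cultures given 20 ng/mL IL-13 for 2, 7 or 21 days. Per the labels, the cells were lifted with the enzyme mix TrypLE for 45 min at 37 °C and captured with the 10x Genomics Chromium Single Cell 3′ kit, version 2. The deposited values are raw UMI counts per gene and barcode, which the authors made with Cell Ranger against GRCh38 and limited to the barcodes that Cell Ranger called as cells. The version of Cell Ranger and of its gene annotation is not given in the sources used here. Every matrix held 33538 genes, of which 33456 were matched by ID to GENCODE 29 for position. Symbols used by 2 genes (24) were kept apart by ID.

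Barcodes with fewer than 500 genes or more than 25% mitochondrial UMIs were left out: 25 in control, 131 at 2 days, 99 at 7 days and 261 at 21 days. Scrublet, with an expected doublet rate of 0.8% per 1000 barcodes, marked 4, 8, 16 and 17 more, in total 45 or 0.531% against expected rates of 0.742%, 2.25%, 1.45% and 2.74%. Doublets left among the kept barcodes are weighed in the closing section. The kept 8422 of 8983 barcodes held 22371664, 54461498, 37111133 and 51969201 UMIs in control and at 2, 7 and 21 days, with medians of 4081, 3733, 4011 and 3789 genes and 8.09%, 8.84%, 8.97% and 8.75% mitochondrial UMIs.

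For the clusters, 2000 variable genes without the IL-13 response, goblet, cell cycle, mitochondrial and ribosomal protein genes were chosen with scanpy, with the libraries as batches. Then followed 30 principal components, 20 neighbours by scikit-learn, and the Leiden method at resolution 1 on a graph of shared neighbours. The libraries were not integrated. No cell annotation by the authors was among the files used here. A marker counted as on in a cluster at 20 CPM or more and 0.25 or more of its level in the cluster where it was highest. A cluster took the name of the class with the largest share of its markers on, if at least 3 markers and a share of 0.33 were on. It was called mixed when secretory and ciliated markers both passed. A rare class, such as ionocyte, neuroendocrine or cycling cells, was taken first where it passed. Shallow clusters without a marker of their class among the 10 leading genes were left unnamed. The share of 0.33 and the rule that sets a cluster aside when its 10 leading genes hold more markers of another class than of its own were chosen after seeing the data. Ciliated-like clusters were 0 (led by LGALS7B, CAPS and CFAP126), 2 (RAET1E, RAB3B), 5 (GSTA1, GSTA2), 11 (IFIT3, SAA2), 12 (IFI44L, IFI6) and 22 (GSTA1, PHKG1). Secretory-like clusters were 4 (PRB2, PRB1, FCGBP, MUC5AC), 6 (VMO1, SCGB1A1), 8 (AZGP1, ATP6V1B1) and 19 (SCGB1A1, BPIFA2), and basal-like clusters were 1 (CAVIN2, HAS3, KRT5), 7 (KRT6A, S100A2, KRT5), 9 (CCL2, FXYD2) and 16 (BPIFB4, KRT15). Mixed clusters were 3 (SCGB3A1, BPIFA1, NOS2), 10 (CEACAM5, MUC5AC) and 14 (GSTA1, BPIFA1). Cluster 13 (SLC26A4, S100A9, CAPN14, SPRR1B, KRT6A) was set aside, 15 (GRP, CALCA) was neuroendocrine-like, 18 (TOP2A, MKI67) cycling-like and 23 (ASCL3) ionocyte-like, and 17 (CFAP70), 20 (ITGA10) and 21 (NME5) were left unnamed. Cluster 15 had 11 ciliated and 10 neuroendocrine markers on at 0.116 of the library median depth, and rare classes were taken first. Clusters 17 and 21 had 15 and 12 ciliated markers on, but their depth was 0.256 and 0.0970 of the library median. They held 41 and 10 of the 3149 kept barcodes at 21 days, against 9 and 2 of 899 in control, which the ciliated-like share leaves out.

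UMIs were summed over the kept barcodes of each library, and of each class with at least 50 cells in both libraries compared, and divided by their total to give CPM. Every IL-13 library was compared with control, and the IL-13 libraries with each other, by the log2 ratio of CPM. A gene counted as measured with 20 UMIs or more over the pair. Intervals at 95% are exact: Poisson for sums, conditional binomial for ratios and Clopper-Pearson for shares. A count of 0 was taken at a floor of 3 counts, over the group, which makes the ratio a bound at that floor. With 0 UMIs in control the lower limit of the 95% interval lies below this bound, as for CST1 at 2 days, with log2 values of 9.20 and 9.50. With 1 library per group no paired or grouped test, replicate check or count of changed genes was possible. The gene lists, 25 with 335 genes of which 3 matched no single gene, the markers, the filters and the rule for named genes were fixed before the data were examined. The rule names in each comparison with control the 12 highest and the 12 lowest ratios among genes with at least 50 CPM in 1 of the libraries and an interval without 0, within a class at 21 days the 5 highest and 5 lowest among genes of at least 100 CPM, always 20 genes of airway biology (1 of them not reported here), and up to 2 highest and 2 lowest members of a list. Mitochondrial and ribosomal genes and genes with clone-based names were not named, and the other list members and cluster-leading genes in the text were chosen after their values were seen. The interval of a list median came from 1000 Poisson redraws of the counts, and its place from 10000 random lists of genes matched within 100 ranks of expression. By that measure the IL-13 response list at 2, 7 and 21 days lay at percentiles 100, 100 and 100, the goblet list at 100, 100 and 100, the ciliated list at 0.170, 0.0100 and 0.0200 and the interferon-stimulated list at 100, 100 and 30.5.

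For the share of cells with a UMI, cells were thinned to 8400 UMIs, and shallower cells were left out. Free RNA was estimated from the UMIs of ciliated genes in basal-like cells. The ratio method was tested on simulated data with 50 genes at each of 4 true folds. For 2 days against control the true folds 4, 2, 0.5 and 0.25 came back as 4.02, 2.00, 0.497 and 0.247 over 16104 genes, for 7 days as 4.02, 1.99, 0.499 and 0.248 over 15668, and for 21 days as 4.00, 2.00, 0.502 and 0.254 over 16064. Of the unchanged genes 95.6%, 95.7% and 95.8% had the truth in their interval, which covers counting error and no spread between cultures. The simulated sums were Poisson draws, as the intervals assume, so this coverage checks the calculation and not the sampling of cells. Alternatives to the scaling, the minimum, the cell filters, the doublets, the clustering and the naming of cells (25 in all) were run, and their effect is given in the closing section. Software was Python 3.11.15, scanpy 1.11.5 (Scrublet included), anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.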

Results

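Droplet RNA sequencing of single cells (10x Genomics 3′ chemistry, version 2) measured transcripts in human airway epithelium grown at an interface of air and liquid, where basal progenitor cells give rise to ciliated and secretory cells that face the air. The cultures came from 1 donor. They were kept as controls without cytokine or given interleukin-13 (IL-13), the type 2 cytokine of allergic airway inflammation, at 20 ng/mL on the apical and the basolateral side, and were collected after 2, 7 or 21 days of IL-13. Each of the 4 groups was 1 library. There was therefore no spread between replicates to hold a difference against, no test was run, and values are given with exact 95% intervals that cover counting error only. The comparisons ask which genes and which classes of cells differed from control as the time of IL-13 grew longer.

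The control library held 928 barcodes with 22605174 molecules counted by unique molecular identifier (UMI). At 2 days there were 2818 barcodes with 54969386 UMIs, at 7 days 1810 with 37828489, and at 21 days 3427 with 53180391. After the filters, 899 control barcodes were kept, with 2679 at 2 days, 1695 at 7 days and 3149 at 21 days. Their median depth was 16964 UMIs in control, 14362 at 2 days, 16421 at 7 days and 14063 at 21 days. Whole-library values are UMI counts per 1000000 UMIs (CPM) over the kept barcodes, and ratios are on the log2 scale against control with the 95% counting interval in parentheses. A list of genes fixed in advance is given by the median log2 ratio of its measured members, with members at 0 UMIs in 1 library taken at a floor of 3 counts, and by how many members were at least 2-fold higher or lower, which is a rule of size and not a call. Positions are on GRCh38 from GENCODE 29, counted from 1.

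After 2 days of IL-13, genes known to respond to this cytokine were already far above control. CCL26, the eosinophil-attracting chemokine eotaxin-3 (ENSG00000006606, chromosome 7, 75769533 to 75789896), was at 1493 CPM against 0.268 in control, a log2 ratio of 12.44 (11.32 to 13.89). Over the whole library the interferon-stimulated list had its highest median at this time. Detoxifying enzymes, led by the glutathione transferase GSTA1, were lower. 17 of 19 measured genes of the IL-13 response list were at least 2-fold higher, 1 (ARG2, a mitochondrial arginase) was at least 2-fold lower, and the list median was 4.26 (3.89 to 4.89).

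Among the 12 most elevated genes at 2 days, POSTN, which encodes the matricellular protein periostin (ENSG00000133110, chromosome 13, 37562583 to 37598844), had 6834 UMIs against 1 in control, a log2 ratio of 11.46 (8.98 to 16.76). CST1, the cysteine protease inhibitor cystatin SN (ENSG00000170373, chromosome 20, 23747553 to 23751268), reached 97.0 CPM with 0 UMIs in control, at least 723-fold higher. The protease inhibitors SERPINB10, SERPINB4 and SERPINB2 had log2 ratios of 6.43, 4.95 and 2.74. NOS2, the inducible nitric oxide synthase, stood at 90.5 CPM against 3.04, and CDH26, a cadherin of epithelium in eosinophilic inflammation, at 359 against 24.8. SPDEF, the transcription factor that drives goblet cell differentiation (ENSG00000124664, chromosome 6, 34537802 to 34556333), was 14.3-fold higher. LGALS7B, a galectin-7 gene with a near-identical paralog, had a log2 ratio of 4.75, the amino acid transporter SLC6A14 one of 2.98 and the monocarboxylate transporter family member SLC16A9 one of 2.87. ALOX15, the lipoxygenase that makes 15-HETE, was at 1929 CPM against 316, and IL13RA2, the decoy receptor of IL-13, had 115 UMIs against 0, at least 15.7-fold higher. CLCA1, a secreted regulator of calcium-activated chloride channels, had 0 UMIs both in control and at 2 days.

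The genes furthest below control at 2 days included several detoxifying enzymes. GSTA1 (ENSG00000243955, chromosome 6, 52791664 to 52803910) was 10.1-fold lower, and S100A9, a subunit of the antimicrobial calprotectin, 6.35-fold lower. The log2 ratios were −1.54 for the retinol-oxidising alcohol dehydrogenase ADH7, −1.48 for the airway cytochrome CYP2F1, −1.40 for the aldehyde dehydrogenase ALDH3A1 and −1.32 for the aldo-keto reductase AKR1C2. SLC34A2, a sodium-phosphate cotransporter, was at 197 CPM against 529. LMCD1, a transcriptional cofactor, PDK4, which inhibits pyruvate dehydrogenase, and NR4A3, an immediate-early nuclear receptor, had log2 ratios of −1.56, −1.48 and −1.42, the secreted protein SPON2 one of −1.42 and the surface antigen PSCA one of −1.30. In the xenobiotic and antioxidant list 6 of 14 measured members were at least 2-fold lower and 0 higher, with a median of −0.63 (−0.66 to −0.60).

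Of the interferon-stimulated list, 11 of 16 members were at least 2-fold higher at 2 days and the median was 1.40 (1.32 to 1.47). IFI44L, an antiviral effector (ENSG00000137959, chromosome 1, 78619922 to 78646145), was at 27.6 CPM against 3.22, and the antiviral genes IFIT2, IFIT3 and IFIT1 had log2 ratios of 2.60, 2.27 and 1.75. The alarmin and chemokine list had a median of 0.39 (0.29 to 0.54), with 2 of 17 members at least 2-fold higher, CCL26 and the granulocyte growth factor CSF3, which had a log2 ratio of 2.21. In the goblet and mucus list 9 of 13 members were at least 2-fold higher, with a median of 1.51 (1.26 to 1.57). They included the mucin chaperone AGR2 at 472 CPM against 166, whereas MUC5AC, the gel-forming mucin of goblet cells, was at 1.21 CPM against 0.358, a log2 ratio of 1.76 (0.70 to 3.03). The club list median was −0.18 (−0.23 to −0.15) and that of the ciliated list −0.26 (−0.29 to −0.24). MUC5B, the other gel-forming mucin of airways, had a log2 ratio of −0.82 over all kept barcodes and of 0.11 without the barcodes that carry secretory and ciliated genes together, called mixed below. Without them POSTN and CST1 had log2 ratios of at least 9.38 and at least 8.23 and LGALS7B one of 4.03.

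At 7 days the medians of the IL-13 response list and of the goblet and mucus list were higher than at 2 days, and several secreted proteins of club cells were below control. CST1 was at 1746 CPM, at least 13023-fold above a control with 0 UMIs, and CCL26 was at 2084 CPM. MUC5AC was at 43.5 CPM against 0.358, a log2 ratio of 6.93 (5.95 to 8.14). SCGB1A1, the club cell secretory protein (ENSG00000149021, chromosome 11, 62405103 to 62423195), was 3.84-fold lower. For the IL-13 response list 17 of 19 measured genes were at least 2-fold higher and 1 (ARG2) lower, with a median of 4.80 (4.47 to 4.98).

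The highest ratios at 7 days again included POSTN at 12.90 (10.42 to 18.21), with SERPINB10 at 7.04, NOS2 at 5.40, LGALS7B at 5.35, SPDEF at 4.87 and SERPINB4 at 4.80. CISH, a feedback inhibitor of cytokine receptor signalling through STAT proteins, was at 56.3 CPM against 0.313. FCGBP, a mucin-like protein of mucus (ENSG00000275395, chromosome 19, 39863323 to 39934626), was 144-fold higher, CEACAM5, a glycoprotein of the apical surface, 108-fold, and the Cdc42 effector CDC42EP5 16.2-fold. In the goblet and mucus list 11 of 13 members were at least 2-fold higher, with a median of 2.16 (2.04 to 2.22). The trefoil peptide TFF3 stood at 521 CPM against 116, and FOXA3, a goblet transcription factor with 1 UMI in control, had a log2 ratio of 7.70 (5.21 to 13.01). Without mixed barcodes the log2 ratios were at least 10.78 for POSTN, at least 12.37 for CST1, at least 4.86 for FOXA3, 6.56 for FCGBP, 6.85 for CISH and 4.56 for LGALS7B.

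Lower at 7 days were SCGB3A1, a secretoglobin and one of the most abundant transcripts of the culture (ENSG00000161055, chromosome 5, 180590103 to 180591540), at 16342 CPM against 52101, and BPIFA1, an antimicrobial secreted protein, at 605 against 2415. The club and host defence list had 6 of 15 members at least 2-fold lower and 2 higher, with a median of −0.94 (−1.02 to −0.80). The members that were higher were PIGR, the receptor that carries IgA across epithelium, with a log2 ratio of 2.07, and lysozyme (LYZ) with 2.76. S100A9, GSTA1, LMCD1, SLC34A2, CYP2F1, NR4A3, SPON2 and AKR1C2 were again among the 12 lowest, between −3.34 for S100A9 and −1.41 for AKR1C2, joined by LYPD2, a small surface protein of the Ly6 family, at −1.79. Without mixed barcodes LYPD2 was at −0.30, LMCD1 at −1.40 and NR4A3 at −0.91, and by the mean of per-cell CPM S100A9 was at −2.66. The interferon-stimulated list had a median of 0.43 (0.29 to 0.56), with 4 of 16 members at least 2-fold higher. Its member IFI27 stood at 274 CPM against 62.4 in control. The xenobiotic list had 5 of 14 members at least 2-fold lower and a median of −0.47, and the alarmin list a median of 0.03 (−0.08 to 0.17).

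At 21 days mucus genes were far above control and most members of the club list were below it. MUC5AC (ENSG00000215182, chromosome 11, 1157953 to 1201138) was at 231 CPM against 0.358 in control, 646-fold higher with a log2 ratio of 9.33 (8.36 to 10.55). SCGB1A1 was at 2.87 CPM against 883, 308-fold lower with a log2 ratio of −8.27 (−8.51 to −8.03). CST1 was at 4167 CPM, at least 31075-fold above control, with 216558 UMIs. Of the goblet and mucus list 12 of 14 measured members were at least 2-fold higher and 0 lower, with a median of 2.91 (2.48 to 3.15).

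The other genes with the highest ratios at 21 days were POSTN at 13.70 (11.22 to 19.00) and CCL26 at 12.70 (11.58 to 14.14), then the salivary proline-rich protein genes PRB2 and PRB1, a pair of close paralogs, at 679.8 and 366 CPM with 0 UMIs in control, at least 5069-fold and 2728-fold higher. FCGBP was 484-fold higher, SERPINB10 161-fold, CEACAM5 156-fold and CISH 237-fold. SLC26A4, the anion exchanger pendrin (ENSG00000091137, chromosome 7, 107660635 to 107717809), was at 51.2 CPM with 3 UMIs in control, a log2 ratio of 8.58 (7.03 to 10.86), and SLC9B2, a sodium-proton exchanger, was at 56.6 against 0.849. Of the genes always reported, SERPINB2 had a log2 ratio of 4.25, ALOX15 of 3.03, FOXA3 of 8.43 (5.95 to 13.74) and SPDEF of 5.63. CLCA1 had 70 UMIs against 0, at least 10.0-fold higher, and IL13RA2 30 UMIs against 0, at least 4.30-fold. Of the IL-13 response list 18 of 20 members were at least 2-fold higher and 0 lower, with a median of 4.49 (4.35 to 4.71). TGM2, a transglutaminase, and ARG2 were its lowest members with log2 ratios of 0.54 and −0.75. Without mixed barcodes SPDEF was at 6.38, MUC5AC over 2 UMIs at 10.28 (8.42 to 13.32) and SLC26A4 over 1 UMI at 9.36 (6.88 to 14.66), and the log2 ratios were at least 11.33 for POSTN, 13.92 for CST1, 11.38 for PRB2, 10.48 for PRB1, 5.85 for FOXA3, 2.29 for CLCA1 and 1.42 for IL13RA2.

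In the other direction BPIFA1 was 16.1-fold lower at 21 days, SCGB3A1 14.9-fold, GSTA1 10.4-fold and CYP2F1 9.01-fold. S100A9, AKR1C2, LYPD2, LMCD1, SLC34A2, the aldo-keto reductase AKR1C1 and ADH7 made up the rest of the 12 lowest, from −2.81 to −1.73. The club and host defence list had 9 of 15 members at least 2-fold lower and a median of −1.11 (−1.12 to −1.01), with LYZ at 135 CPM against 5.50 and PIGR at 4247 against 853 in the opposite direction. MUC5B had a log2 ratio of −1.88. Mixed barcodes, which held 46.7% of kept UMIs in control and 14.0% at 21 days, weigh on these values: without them the log2 ratios were −3.30 for BPIFA1, −2.35 for CYP2F1, −0.33 for LYPD2, −1.34 for LMCD1 and −0.53 for MUC5B. The xenobiotic list had 6 of 14 members at least 2-fold lower and a median of −0.47. For the interferon-stimulated list the median was −0.07 (−0.11 to 0.02), with 2 members at least 2-fold higher and 2 lower. The alarmin and chemokine list had a median of −0.37 (−0.53 to −0.30), with IL33 at −1.46 and IL1A at −1.20.

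**Figure D1:**
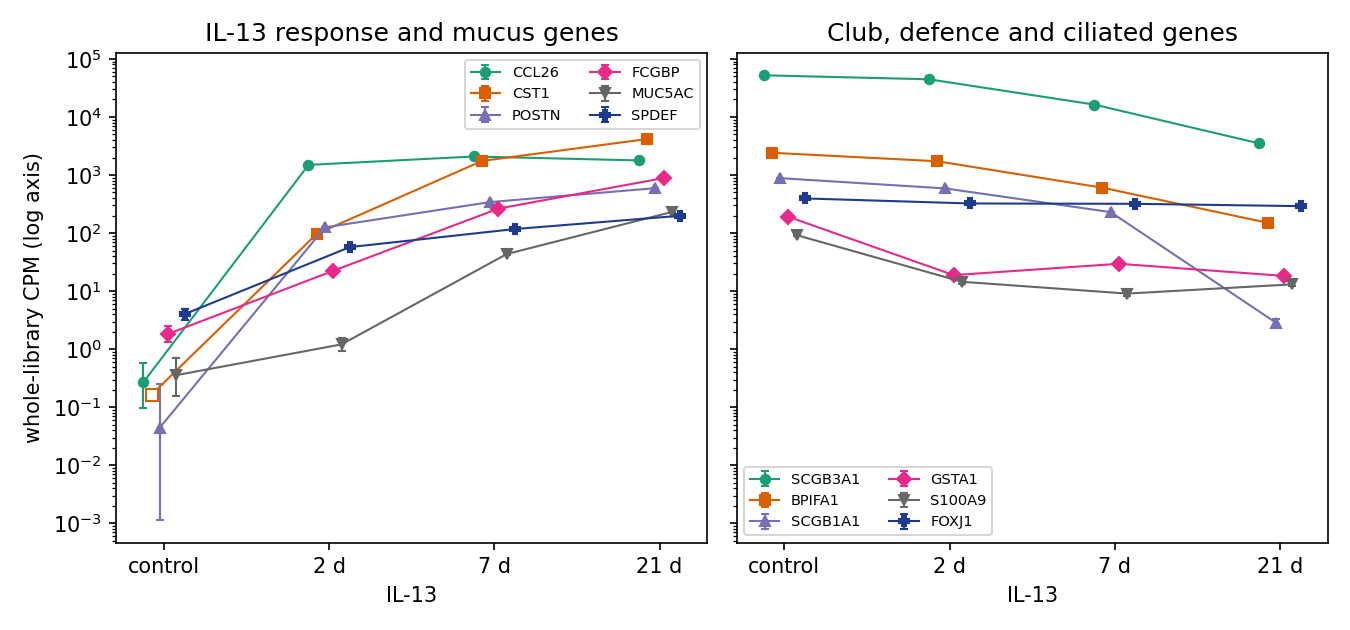
Whole-library CPM on a log axis for 12 named genes in the control library and after 2, 7 and 21 days of IL-13, 1 library each, with bars for exact 95% Poisson intervals of the counts and an open symbol at the upper interval bound where a gene had 0 UMIs. CCL26 stood at 1493, 2084 and 1782 CPM, MUC5AC at 1.21, 43.5 and 231 CPM at 2, 7 and 21 days, and SCGB1A1 at 587, 229.9 and 2.87.

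Between the treated libraries, interferon-stimulated genes had their highest list median at 2 days over the whole library, and mucus genes at 21 days. In secretory-like cells the interferon-stimulated list median was instead lowest at 2 days and highest at 21 days, with a median of 0.36 (0.31 to 0.59) between them, against 0.29 for all genes of at least 10 CPM in that comparison. The list median of basal-like cells against control was likewise lowest at 2 days and highest at 21 days. Between 2 and 21 days the goblet and mucus list had a median of 1.71 (1.59 to 1.82), the IL-13 response list 0.78 (0.71 to 0.85), the club list −0.54 (−0.93 to −0.29), the interferon-stimulated list −0.88 (−0.99 to −0.84) and the alarmin list −0.87 (−0.90 to −0.70). From 7 to 21 days the goblet list median was 0.39 (0.36 to 0.76), and MUC5AC was 5.30-fold higher while CCL26 had a log2 ratio of −0.23. CST1 was 43.0-fold higher at 21 than at 2 days.

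Genes of ion and water transport were in part far above control. At 21 days 8 of 22 measured members were at least 2-fold higher and 1 lower, with medians of 0.13, 0.26 and 0.31 at 2, 7 and 21 days. Higher at 21 days were SLC26A4, the calcium-activated chloride channel ANO1 at 10.4 CPM against 0.313, carbonic anhydrase CA2 at a log2 ratio of 4.98, SLC6A14 at 4.22 and the basolateral chloride loader SLC12A2 at 150.1 CPM against 24.5. ATP12A, the non-gastric proton pump that acidifies airway surface liquid, was at 133 CPM in control, 239.7 at 2 days, 316 at 7 days and 324 at 21 days. CFTR, the anion channel mutated in cystic fibrosis, was rare throughout, at 1.39, 1.73, 2.10 and 2.37 CPM. Its log2 ratios of 0.32, 0.60 and 0.77 at 2, 7 and 21 days were 1.02, 1.30 and 1.42 with a stricter filter of cells, and that at 7 days was −0.51 without mixed barcodes. The potassium channel KCNMA1 had a log2 ratio of −1.52 at 21 days and the water channel AQP5 −1.79 at 2 days.

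The receptors of IL-4 and IL-13 and their STAT6 pathway had list medians of −0.04, −0.07 and 0.08 at 2, 7 and 21 days. The members at least 2-fold higher at 21 days were IL13RA2, CISH, SOCS1, a feedback inhibitor of JAK kinases with a log2 ratio of 3.57, and the shared receptor chain IL4R at 1.40, whereas IL2RG was at −1.59 and STAT6 at 0.12. Cell cycle genes had medians of 0.61, 1.30 and 1.28, with 9 of 14 at least 2-fold higher at 21 days. MKI67, a marker of dividing cells, was at 0.626 CPM in control and 7.27 at 21 days, with a log2 ratio of 3.54 that was 2.85 without mixed barcodes, and the licensing factor MCM2 had a log2 ratio of −0.32. Only 3 control cells were cycling-like, against 38 at 21 days, and how far these ratios rest on those few cells was not tested. Neuroendocrine genes had medians of 2.94, 3.83 and 2.75, with 8 of 9, 8 of 9 and 6 of 7 measured members at least 2-fold higher. Those UMIs lay mostly in a small set of barcodes: of the 789 UMIs of the peptide gene GRP at 7 days, 774 were in 79 neuroendocrine-like barcodes with a median of 1775 UMIs, while 26 barcodes of that library had UMIs of at least 2 neuroendocrine genes. Control had 2 GRP UMIs over 899 kept barcodes, and 0 of these had UMIs of at least 2 neuroendocrine genes, which allows a share of up to 0.334%. The 17 control barcodes in the neuroendocrine-like cluster held 0 GRP and 0 CALCA UMIs at a median of 2058 UMIs.

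The ciliated list median was −0.26, −0.34 and −0.35 at 2, 7 and 21 days, which lay at percentiles 0.170, 0.0100 and 0.0200 of random lists of like expression, and FOXJ1, the master regulator of motile cilia (ENSG00000129654, chromosome 17, 76136333 to 76141299), was at 395 CPM in control and 291 at 21 days. Genes of the onset of multiciliation had medians of −0.33, −0.30 and −0.59, with the regulator FOXN4 at −1.79 at 21 days. Basal markers had medians of −0.10, −0.11 and 0.07, in which the hemidesmosomal collagen COL17A1 was at 2.19 and the keratin KRT15 at −1.31 at 21 days. KRT5, the keratin of basal cells (ENSG00000186081, chromosome 12, 52514575 to 52520687), had a log2 ratio of 0.56 at 21 days, and of −0.047 without the barcodes of mixed profile. Squamous and suprabasal genes had medians of −0.11, −0.57 and −0.31, with the mucosal keratin KRT4 at −2.07 and the wound keratin KRT6A at 1.82 at 21 days. Viral entry genes had medians of 0.11, 0.02 and −0.05, with the protease TMPRSS2 at 29.6 CPM in control and 45.7 at 21 days, and DPP4, the MERS coronavirus receptor and an IL-13 response gene, at 0.626 and 39.4.

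The medians of the remaining lists at 2, 7 and 21 days were 0.12, 0.06 and 0.16 for the unfolded protein response, −0.10, −0.17 and −0.12 for dissociation stress, −0.18, −0.17 and 0.05 for the Notch pathway, and −0.20, −0.23 and −0.27 for cell junctions. Lipid mediator genes had medians of 0.23, −0.02 and −0.07, with ALOX15 at the top and the secreted phospholipase PLA2G2A, at 0 CPM against 2.41, at the bottom at 21 days. Ionocyte genes had medians of 0.19, −0.73 and 0.15, and FOXI1, the ionocyte transcription factor, was at 0.849, 0.955, 0.189 and 0.808 CPM over the series, with a log2 ratio of −0.07 at 21 days that was −0.95 without mixed barcodes. Tuft cell genes had medians of −0.26, −0.12 and −0.93 over 5, 5 and 4 measured members. The immune cell and fibroblast lists each had 2 measured members, too few for a median: CD68 had a log2 ratio of −0.69 at 21 days, CD14 of 0.07, COL1A1 of 1.27 and FBLN1 of −0.86, and the pan-leukocyte gene PTPRC had 1, 0, 1 and 0 UMIs. The endothelial list had medians of 1.39, 2.54 and 2.95 over 4, 5 and 5 members, led by VWF at 13.9 CPM against 0.536, of which 309 of 720 UMIs at 21 days were in secretory-like cells.

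Clustering of all kept barcodes gave 24 clusters, which were named from markers fixed in advance. Secretory-like cells made up 9.90% (8.03 to 12.04%) of kept barcodes in control, 10.5% (9.39 to 11.8%) at 2 days, 15.6% (13.9 to 17.4%) at 7 days and 27.7% (26.1 to 29.3%) at 21 days. Ciliated-like cells made up 41.2% (37.9 to 44.5%), 41.0% (39.1 to 42.9%), 32.3% (30.1 to 34.6%) and 37.2% (35.5 to 38.9%) in the same order, and basal-like cells 20.6% (18.0 to 23.4%), 22.4% (20.9 to 24.1%), 25.5% (23.5 to 27.7%) and 20.1% (18.7 to 21.5%). The class of mixed barcodes held 22.9% (20.2 to 25.8%) of control barcodes, 18.1% (16.6 to 19.6%) at 2 days, 16.9% (15.1 to 18.7%) at 7 days and 7.56% (6.66 to 8.54%) at 21 days, with median depths of 50516, 40686, 41790 and 29580 UMIs. Cycling-like cells were 0.334%, 0.747%, 1.24% and 1.21% of the libraries, neuroendocrine-like barcodes 1.89%, 2.54%, 4.66% and 0.445% (with 0, 5, 26 and 3 barcodes of the libraries having UMIs of at least 2 neuroendocrine genes), and ionocyte-like cells 0.222%, 0.261%, 0.118% and 0.254%. The cycling-like shares rest on 3 cells in control and on 20, 21 and 38 at 2, 7 and 21 days. The neuroendocrine-like cluster was shallow and had 11 ciliated markers on beside its 10 neuroendocrine ones. Cluster 13 had 9 secretory and 5 squamous markers on, but its 10 leading genes, with SLC26A4 first, held 2 squamous and 0 secretory markers. It was therefore set aside and held 1.78%, 2.84%, 2.89% and 2.99%, and unnamed clusters held 1.22%, 1.61%, 0.767% and 2.57%. No cluster was squamous-like, tuft-like, deuterosomal-like or of immune cells.

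These shares depend on how barcodes are named. Counting the mixed barcodes as secretory-like turns the difference of secretory-like cells from control from 5.68 to −0.366 percentage points at 7 days and from 17.8 to 2.44 at 21 days, and giving each cell the class of its highest marker score makes it 3.12 at 21 days. The difference of ciliated-like cells at 7 days, −8.83 percentage points, turns to 3.50 with marked doublets kept and no cluster set aside. At 21 days it turns from −3.94 to 2.10 over all deposited barcodes with no cluster set aside. Markers of secretory cells such as SCGB1A1 and SCGB3A1 were themselves lower in the treated libraries.

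**Figure D2:**
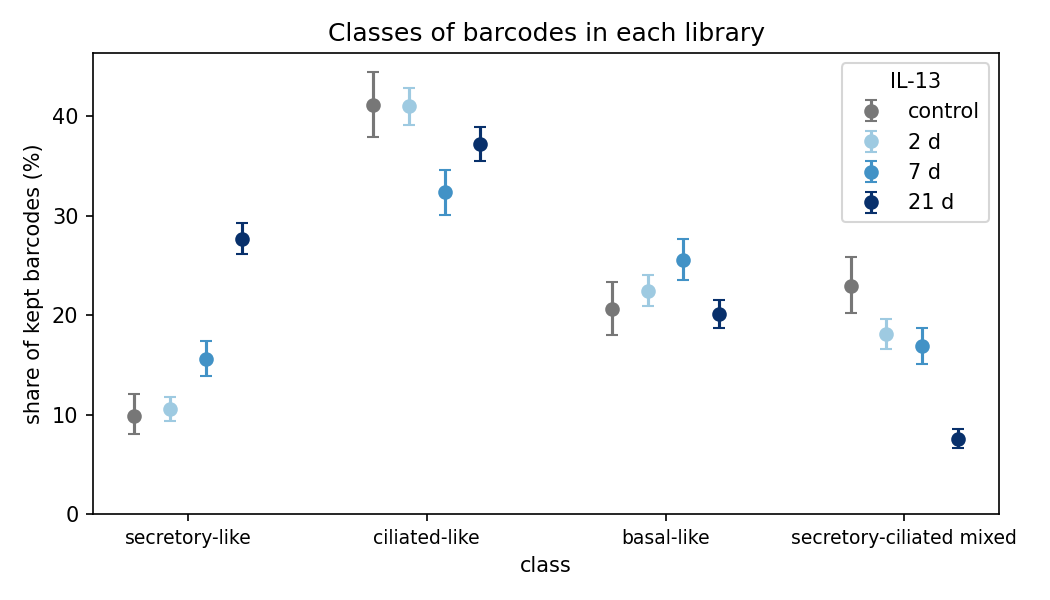
Share of kept barcodes in 4 classes in the control library and after 2, 7 and 21 days of IL-13, 1 library each, with bars for exact 95% Clopper-Pearson intervals. The secretory-like share stands at 9.90% in control and 27.7% at 21 days, and the mixed share at 22.9% and 7.56%.

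Within secretory-like cells the goblet list median was higher than in control at each time. Of the goblet and mucus list 14 of 14 measured members were at least 2-fold higher at 21 days, and the median was 2.11 (1.69 to 2.35) at 2 days, 3.69 (2.78 to 4.39) at 7 days and 4.06 (3.41 to 4.66) at 21 days. MUC5AC was at 576 CPM with 0 UMIs in control, at least 437-fold higher, and SCGB1A1 was at 5.36 CPM against 2849.7, 532-fold lower. Secretory-like cells came mostly from clusters 19 and 8 in control and from clusters 4, 8 and 6 at 21 days, so the libraries are compared over different clusters and part of a difference may come from how these were named.

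The highest ratios in secretory-like cells at 21 days were those of CST1 at 10857 CPM, CCL26 at 3127, PRB2 at 1921 and PRB1 at 1046, each with 0 UMIs in control and at least 8238-fold, 2373-fold, 1458-fold and 794-fold higher, and of FCGBP at 2335 CPM against 1 UMI, a log2 ratio of 12.38 (9.90 to 17.68). PRB2, PRB1, FCGBP and CST1 also lead cluster 4. TFF3 was at 2677 CPM against 14.9, SPDEF at 490.3 against 9.23 and LYZ at 355 against 3.95. The lowest were SCGB1A1, S100A9 at −4.63, SCGB3A1 at −4.08, BPIFA1 at −3.84 and CYP2F1 at −3.07. With classes given by marker score FCGBP was at 10.61, SCGB1A1 at −8.09 and S100A9 at −2.60, and S100A9 was at −6.39 with each library clustered alone. The IL-13 response list had a median of 5.17 (4.80 to 5.54) at 21 days and the club list −0.92 (−1.27 to −0.67), with 6 of 14 club members at least 2-fold lower and 3 higher. Genes of the unfolded protein response had medians of 0.05, 0.38 and 0.61, with the endoplasmic reticulum chaperone HSPA5 at 197 CPM against 88.3. Squamous genes had a median of −1.29 (−1.77 to −0.89) and the alarmin list −0.58 (−0.69 to −0.38), with the cytokine IL6 at −2.52. The interferon-stimulated list had medians of −0.03, 0.27 and 0.43 (0.29 to 0.65) at 2, 7 and 21 days, and after thinning 27 of 252, 57 of 254 and 255 of 822 of these cells lay above the 95th percentile of control for its UMIs. Ratios in this class are to be read against the median over all genes of at least 10 CPM, which was 0.18 at 7 days and 0.34 at 21 days. Within cluster 8 alone, which holds cells of every library, the goblet list median at 21 days was 2.17.

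Ciliated-like cells carried the IL-13 response too, with 15 of 17 measured members at least 2-fold higher at 21 days and medians of 3.52 (3.10 to 3.91), 3.99 (3.60 to 4.70) and 3.39 (3.20 to 3.71) at 2, 7 and 21 days. At 2 days their interferon-stimulated list had a median of 1.88 (1.74 to 2.02) with 13 of 15 members at least 2-fold higher, and medians of 0.59 (0.40 to 0.81) at 7 days and −0.05 (−0.26 to 0.02) at 21 days. After thinning 217 of 1005, 77 of 530 and 145 of 1088 ciliated-like cells at 2, 7 and 21 days lay above the 95th percentile of control for its UMIs. The alarmin list stood at 1.45 (1.27 to 1.68) at 2 days and −0.51 (−0.69 to −0.36) at 21 days. Ciliated-like cells came mostly from cluster 5 in control and from clusters 0, 2, 11 and 12 in the treated libraries, and clusters 11 and 12 are themselves led by interferon-stimulated genes.

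The highest ratios in ciliated-like cells at 21 days were those of CST1 at 194 CPM with 0 UMIs in control, at least 377-fold, SERPINB10 at 7.76, LGALS7B, which also leads cluster 0, at 7.10, CDH26 at 3.39 and SLC16A9 at 3.25. SCGB1A1 at −7.28, SCGB3A1 at −3.55 and BPIFA1 at −3.11 were the lowest together with GSTA1, at 37.2 CPM against 324, and ADH7, at 65.3 against 287. Secretory transcripts in this class include free RNA released by other cells, which was estimated at 3.25% of UMIs in control and 3.05% at 21 days and would give CST1 127 CPM there. SCGB3A1 was at −2.88 with free RNA subtracted, and with classes given by marker score it was at −4.21 and BPIFA1 at −5.45. The ciliated list itself had medians of −0.29, −0.19 and −0.17, and the goblet list 1.44 (1.29 to 2.07) at 21 days. KRT5 had log2 ratios of 1.06, 0.87 and 0.89 in this class, and of −0.17, −0.12 and −0.35 when classes were given by marker score.

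Most POSTN UMIs at 21 days, 20498 of 30856, were in basal-like cells. In these cells POSTN reached 2316 CPM at 21 days with 0 UMIs in control, at least 2482-fold, and CCL26 3632 CPM with 3 UMIs in control, a log2 ratio of 11.93 (10.38 to 14.20). The IL-13 response list had medians of 3.37 (3.17 to 3.88), 3.56 (3.29 to 4.05) and 4.19 (3.48 to 4.39), with 16 of 18 members at least 2-fold higher at 21 days. Control basal-like cells came mostly from cluster 16, which is of the control library alone, and treated ones from clusters 1, 7 and 9. Next in rank were CST1 at 336 CPM against 0 UMIs, SERPINB10 at 7.28 and CDH26 at 5.51, while SCGB3A1 at −5.06, FXYD2, a subunit of the sodium pump, at −4.51, the defensin DEFB1 at −4.43, S100A9 at −3.14 and AKR1C2 at −2.99 were the lowest. Free RNA would give SCGB3A1 1691 CPM in control and 107 at 21 days, where basal-like cells had 3035 and 90.9, and CST1 127 CPM at 21 days. Basal markers had medians of −0.21, −0.51 and 0.23, squamous genes −0.51, −1.22 and −0.67, and interferon-stimulated genes 0.66, 0.90 and 1.00. After thinning 25 of 584, 32 of 427 and 39 of 597 basal-like cells at 2, 7 and 21 days lay above the 95th percentile of control for interferon-stimulated UMIs, as did 7 of 176 in control. The median of all genes in this class was 0.17 at 21 days. In the mixed barcodes the goblet list had medians of 1.64, 2.26 and 2.35 and the IL-13 response list 5.03, 5.26 and 4.76. Of the 206 control mixed barcodes 202 came from cluster 14, while treated ones came from clusters 3 and 10, and MUC5AC is among the leading genes of cluster 10. At 21 days the highest ratios in mixed barcodes were those of CST1, PRB2 and PRB1, with 0 UMIs in control and log2 ratios of at least 14.31, at least 11.35 and at least 10.45, of CCL26 over 3 UMIs at 12.27 (10.72 to 14.55) and of POSTN over 1 UMI at 11.48 (8.996 to 16.78). The lowest were those of SCGB1A1 at −7.45, BPIFA1 at −3.90, SCGB3A1 at −3.88, CYP2F1 at −3.21 and GSTA1 at −3.20.

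**Figure D3:**
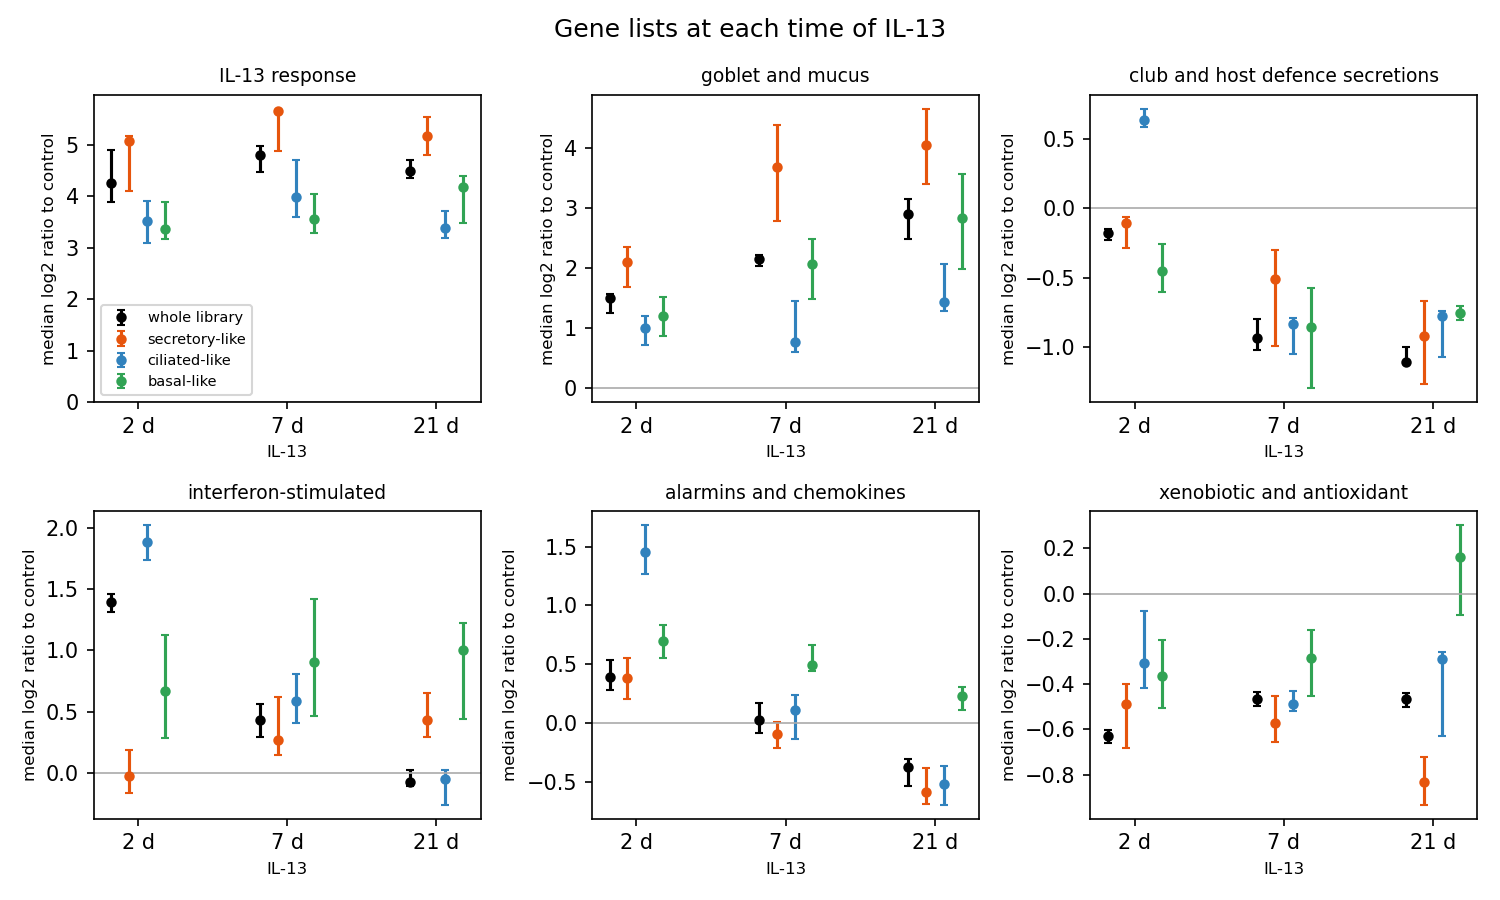
Median log2 ratio to control of 6 gene lists after 2, 7 and 21 days of IL-13 over the whole library and within secretory-like, ciliated-like and basal-like cells, 1 library per time, with bars for 95% intervals from redrawn counts. The interferon-stimulated list is highest in ciliated-like cells at 2 days, at 1.88, and the goblet and mucus list in secretory-like cells at 21 days, at 4.06.

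More cells held goblet transcripts after 7 and 21 days of IL-13 than in control, with the highest shares in secretory-like cells and mixed barcodes. After thinning every cell to 8400 UMIs, MUC5AC was seen in 0.243% of control cells, 0.661% at 2 days, 8.08% at 7 days and 25.8% at 21 days. Among secretory-like cells it was seen in 0 of 81 control cells, which allows up to 3.70% with a UMI, and in 1.19%, 14.2% and 50.2% after 2, 7 and 21 days, or 1.42%, 22.0% and 56.8% without thinning. In mixed barcodes it was seen in 0.498%, 1.04%, 23.2% and 51.7% in control and after 2, 7 and 21 days. In basal-like cells, which should lack it, MUC5AC was seen in 9.72% at 21 days, and 13.9% unthinned, at a median depth of 13257 UMIs against 15486 in secretory-like cells. SPDEF was seen in 8.64% of secretory-like cells in control and 75.7% at 21 days (14.6% and 80.8% unthinned), with 8.54% of basal-like cells at 21 days. For FCGBP the shares of secretory-like cells were 0% and 70.4% (1.12% and 77.6% unthinned), with 19.6% of basal-like cells. SCGB1A1 went the other way, from 59.3% of secretory-like cells in control to 3.16% at 21 days (70.8% and 5.05% unthinned), with 15.3% and 0% of basal-like cells. IFIT1 was seen in 6.38% of ciliated-like cells in control, 25.5% at 2 days, 16.2% at 7 days and 8.09% at 21 days (13.8%, 32.5%, 23.7% and 14.1% unthinned), against 2.74% of basal-like cells at 2 days, at median depths of 12036 and 13458 UMIs. Thinning left out 75, 257, 123 and 273 shallower cells of the control, 2-day, 7-day and 21-day libraries.

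The shares of ion transport and mucin UMIs in each class differed between libraries, as did the sizes of the classes. At 21 days 70.8% (70.0 to 71.6%) of MUC5AC UMIs were in secretory-like cells and 22.5% in mixed barcodes, whereas at 7 days mixed barcodes held 70.8% and secretory-like cells 23.7%. Per cell, mixed barcodes held more at both times, 4 against 1.45 UMIs at 7 days and 11.4 against 9.74 at 21 days, but they are deeper, and in CPM the values were 91.6 against 62.8 and 373 against 576. Of 31 CFTR UMIs in control, 2 ionocyte-like cells held 17 or 54.8% (36.0 to 72.7%), and mixed barcodes 35.5% (19.2 to 54.6%). At 7 days mixed barcodes held 62.8% (51.1 to 73.5%) of CFTR UMIs. After 21 days ionocyte-like cells held 24.4% (17.1 to 33.0%), secretory-like cells 46.3% (37.3 to 55.6%) and mixed barcodes 17.1% (10.9 to 24.9%). All intervals of UMI shares here treat UMIs as independent and leave out the sampling of cells. The ionocyte-like shares rest on 2 cells in control and 8 at 21 days, so a difference between them is not settled. SLC26A4 UMIs at 21 days lay to 67.6% (65.8 to 69.4%) in the set-aside cluster 13, which SLC26A4 leads, and to 20.1% (18.6 to 21.6%) in secretory-like cells. ATP12A UMIs were 20.6% in secretory-like cells and 61.2% in mixed barcodes in control, against 58.0% and 18.2% at 21 days, or per cell 6.90 and 8.85 UMIs in control against 11.2 and 12.9. Within secretory-like cells CFTR had 0 UMIs in control and was at 3.87 CPM at 21 days, at least 2.93-fold higher, but its log2 ratio was −0.62 when each library was clustered alone.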

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

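Each value below was a list median that lay on opposite sides of 0, by at least 0.5 log2, at different times or in different classes among 252 medians looked at, and no test was chosen after the result was seen because these differences were not tested. The club and host defence list in ciliated-like cells had a median log2 ratio to control of 0.64 at 2 days, −0.84 at 7 days and −0.78 at 21 days, a difference between times. In ciliated-like cells at 2 days the antimicrobial protein MSMB stood at 1.32, SCGB3A1 at 0.64 and SCGB1A1 at 0.03 (−1.14 with doublets kept), and at 21 days SCGB3A1 at −3.55. SCGB3A1 in control was at 1.45 times the level that free RNA would give by the share seen in basal-like cells, and at 0.902 times by that in secretory-like cells. The alarmin and chemokine list in ciliated-like cells had a median of 1.45 at 2 days, with the neutrophil chemokines CXCL6 at 4.33 and CXCL1 at 1.74, and a median of −0.51 at 21 days, with the chemokine CCL20 at −1.66. The basal list at 7 days had a median of 0.53 (0.10 to 0.83) in ciliated-like cells, −1.09 (−1.43 to −0.49) in secretory-like cells and −0.51 (−0.72 to −0.19) in basal-like cells, a difference between classes. KRT5 stood at 0.87, −2.30 and 0.03 in these classes, and by marker score at −0.12 in ciliated-like and −0.55 in secretory-like cells, where it was −4.43 with free RNA subtracted, and COL17A1 at 2.82, 3.75 and 0.66.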

How the results depend on the processing

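Every alternative that touches the mixed barcodes, the set-aside cluster, cluster 8 alone or the removal of the highest doublet scores was chosen after the result was seen, and the others were fixed beforehand. Of the 27 values of the IL-13 response list median under alternatives, 25 stayed within the counting interval, as did 20 of 27 for the goblet list and 19 of 27 for the ciliated list, and none reversed. Median-of-ratios scaling gave a goblet list median of 1.57 at 2 days and ciliated list medians of −0.20 at 2 days and −0.29 at 7 days. The mean of per-cell CPM gave goblet medians of 2.23 at 7 and 3.26 at 21 days and ciliated medians of −0.47 and −0.46. With no minimum of UMIs the 7-day medians were 1.86 for the goblet and 4.38 for the IL-13 response list, because members with fewer UMIs then enter, and without the 20 genes with the most UMIs the ciliated median was −0.41 at 21 days. Without mixed barcodes the goblet medians were 1.74, 2.41 and 3.73 at 2, 7 and 21 days, the ciliated medians −0.31, −0.46 and −0.43 and the 7-day IL-13 response median 5.19, while MUC5B at 2 days (0.11) and KRT5 at 21 days (−0.047) reversed. Class shares moved with the clustering and with how barcodes were named. The ciliated-like difference in percentage points was −4.75 at 2 days by highest marker score, −14.5 at 7 and −13.1 at 21 days with mixed barcodes left out, and −5.02, −14.9 and −19.3 with them counted as ciliated-like. With no cluster set aside it was 4.84, 2.56 and 2.10 over all deposited barcodes and 3.50 at 7 and 1.03 at 21 days with doublets kept, reversed at 7 and 21 days. The secretory-like difference was 6.91 at 2 days at resolution 2, −3.17 at 2 and 14.7 at 21 days with each library clustered alone, 3.12 at 21 days by marker score, and −4.22, −0.366 (reversed) and 2.44 with mixed barcodes counted in. The basal-like difference at 21 days was −4.98 with mixed barcodes left out. Within secretory-like cells the goblet median was 2.40 at 7 and 3.24 at 21 days by marker score and 2.17 in cluster 8 at 21 days, there over only 29 control cells. CFTR in secretory-like cells reversed to −2.11 and −0.62 at 2 and 21 days with each library clustered alone, and KRT5 in ciliated-like cells to −0.17, −0.12 and −0.35 at 2, 7 and 21 days by marker score. Unless stated, the cause was not tested. Of the named-gene values 135 of 936 over the whole library moved beyond their interval without reversing, as did 62 of 290 in secretory-like, 28 of 282 in ciliated-like and 15 of 243 in basal-like cells. Shares of cells with a UMI depend on depth: 30 of 32 moved without thinning or at 4200 UMIs. No paired analysis was possible because each group was 1 culture.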

Other observations

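Within secretory-like cells at 21 days, 10 of 22 measured members of the ion and water transport list were at least 2-fold higher and 1 lower, with medians of 0.70, 0.57 and 0.65 at 2, 7 and 21 days. The log2 ratios at 21 days were 5.74 for SLC6A14, 5.13 for CA2, 3.70 for the sodium-proton exchanger SLC9A3, 3.67 for SLC12A2 and 1.30 for ATP12A. The epithelial sodium channel subunits SCNN1A, SCNN1B and SCNN1G had 0.01, −0.51 and −0.44. IL4R had a log2 ratio of 2.25 in this class, and the receptor and STAT6 list medians of 0.42, 0.30 and 0.46. Over the whole library NOTCH3, a Notch receptor of the basal and suprabasal layer, had −1.50 at 21 days and HPGD, which degrades prostaglandins, 1.73.

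Barcodes with UMIs of at least 2 of 11 neuroendocrine genes (the list without PCSK1N) numbered 0 in control, 5 at 2 days, 26 at 7 days and 3 at 21 days, among 899, 2679, 1695 and 3149 kept barcodes. Control's 0 allows a share of up to 0.334%, and the shares were 0.187% at 2 days, 1.53% at 7 days and 0.0953% at 21 days, above that limit at 7 days alone, where these barcodes were shallow, with a median of 1397 UMIs against 19368 at 2 and 17514 at 21 days. CALCA, the gene of the peptide CGRP, had 0, 488, 576 and 71 UMIs in the same order. No explanation was tested.

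Of the tests that follow, those of random co-capture, of dissociation stress, of IL-13 on ciliated-like cells at large, of subtracted secretory-like RNA, of members above 3 times the free RNA level and of all members in shallower cells were chosen after the result was seen. The mixed barcodes, 22.9% of control and 7.56% of the 21-day library, carried secretory and ciliated genes together at 1.51 and 1.04 times the sum of the median UMIs of both classes. Random capture of 2 cells in a droplet would give the lowest share in control, which has the fewest barcodes, but the control share was 3.03 times that of 21 days (2.37 to 3.88). Single cells on the way from a secretory to a ciliated state would be rich in multiciliation onset genes, yet these reached at most 0.661 of their level in the higher class, with 0.594 the lowest. At most 0.0538% of genes lay more than 2-fold outside the range of both classes, which secretory and ciliated cells left attached to each other would give. Single cells that carry both sets of genes would give it too, because the clusters were called mixed when both sets of markers passed. This value therefore cannot tell these sources apart. Attachment stays a hypothesis, and whether IL-13 changed how well cells came apart was not tested.

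Interferon-stimulated genes in ciliated-like cells at 2 days, with a median of 1.88, stayed at 1.90 over 15 measured members with free RNA subtracted. The share subtracted was 3.13%, which could take little off the list in the class where it was highest. This test could therefore hardly have come out otherwise, and it speaks only to free RNA at that estimated share. The dissociation stress list had a median of −0.21 (−0.25 to −0.13) in the same cells, which argues against stress of dissociation. For an action of IL-13 on ciliated-like cells at large, the median cell had 1.06 times the list UMIs of the control's. The cell at the 90th percentile had 2.25 times, and 21.6% of cells lay above the 95th percentile of control (14.5% at 7 and 13.3% at 21 days). These summed UMIs cannot decide the question, because members with many UMIs outweigh the others. In basal-like cells at 21 days the median cell was level with control, although the list median was above it. Summed UMIs were high in a part of the ciliated-like cells, while interferon genes themselves such as IFNL1 and IFNB1 had 0 UMIs. What set that part apart stays open with 1 culture, and so does a response to IL-13, in some cells or at large.

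Goblet and mucus genes at 21 days had medians of 2.84 in basal-like and 1.44 in ciliated-like cells. With free RNA subtracted they were 1.89 over 9 members and 1.30 over 12, but the share subtracted had been estimated from ciliated genes. As a second bound, the largest share of secretory-like RNA that every member allows, 1.48% and 1.57%, was taken off the 21-day counts instead. The medians were then 0.44 (−0.18 to 1.14) and 0.81 (0.45 to 1.32), so for the list as a whole free RNA and expression in these cells cannot be told apart. Of the members at least 2-fold above control, 2 of 7 in basal-like cells lay above 3 times the free RNA level, GCNT3 at 8.44 and AGR2 at 5.14 times, and 4 of 8 in ciliated-like cells, with AGR2 at 20.6 and TFF3 at 13.8 times. Unmarked doublets with secretory-like cells would be the deeper barcodes, but the shallower part of the cells had medians of 2.64 over 6 members and 2.33 (1.20 to 2.46) over all 9 in basal-like cells, which argues against doublets as the whole cause there, while 1.45 over 10 members and 1.41 (0.58 to 1.54) over all 12 in ciliated-like cells leave them open. A response of these cells to IL-13 stays open with 1 culture.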
